A study of Mus musculus with 4 samples.

How the data were processed

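CD45-sorted leukocytes of the mouse colon were profiled by droplet single-cell RNA-seq in 2 control and 2 stress libraries. The deposited matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger against the mm10 build and not normalised further. The submitters' processing notes name Cell Ranger 5 in one place and 5.0 in another, while the matrix headers name software 3.1.0, and the annotation release is not given in the sources used here. The 4 matrices share 31053 genes, 36 symbols belong to more than 1 gene identifier, and no barcode has fewer than 500 UMIs, so empty droplets, and with them the free RNA of each library, could not be measured directly. Coordinates are 1-based and come from GENCODE vM21 on GRCm38, the same assembly as mm10. Of the 31053 identifiers 30934 are in that annotation, 30468 of them with the same symbol, and the genes with coordinates in the text are all protein coding. Genes were tested by identifier, and symbols are those of the files. Reads of near-identical copies (Iglc1, the Ly6, H2-Q and Klrb1 families, Hist1h2ap) may be exchanged between genes.

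Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs, which left 2546, 5436, 8319 and 4127. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. Where its automatic threshold marked under 0.5% or over 20% of a library, the expected share with the highest scores was left out. The automatic threshold marked 0.24, 1.71, 0 and 0% and was therefore used in control 2 alone, and 60, 93, 683 and 185 cells were left out in all. The kept cells held 11902119, 19616749, 29296518 and 32892221 UMIs and medians of 1170, 1081, 918 and 1518 genes.

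Counts were log-normalised and clustered without batch integration on 2000 variable genes, 30 principal components and a graph of 20 neighbours weighted by shared neighbours, with Leiden at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19). Immunoglobulin and T cell receptor segments and mitochondrial, ribosomal and sex chromosome check genes were kept out of the clustering genes. Clusters were named from marker lists, and the suffix -like marks that no protein was measured. B cell-like cells were clusters 0 (Fcmr), 1 (Scd1), 6 and 8 (both Cr2), T cell-like cells clusters 3 (Gzma), 7 (Lef1), 9 (Icos), 11 (Cd8b1) and 13 (Izumo1r), and plasma cell-like cells clusters 2 and 19 (both Jchain). Single clusters gave cDC2-like (12, Cd209a), NK or ILC1-like (14, Ncr1), fibroblast-like (15, Dcn), ILC2-like (17, Il1rl1), cDC1-like (20, Xcr1), neutrophil-like (21, S100a9) and epithelial-like cells (22, Krt8). Clusters 5 (Egr3), 10 and 16 (Top2a) stayed unnamed. Cluster 4 (Lyz2, 1270 cells) mixed monocytes and macrophages and was divided by the clusters of resolution 2.0 into 956 monocyte-like cells, led by Chil3, and macrophage-like cells, which with cluster 18 (C1qa, 198 cells, median 936.5 UMIs) made 510. That division was chosen after seeing the data. The cDC2-like class holds 56 plasmacytoid DC-like cells of 435, most of them from stress libraries, and its cluster genes held Igha. Genes that define a cluster or are markers of a class are not reported as results in it.

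Counts were summed per library and class, so that libraries and not cells are the replicates. Each class with at least 30 cells in every library was fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM, filterByExpr by group, robust quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05. The sums held between 205872 UMIs (NK or ILC1-like) and 32892221 UMIs (all cells). In cluster 9 the prior degrees of freedom were infinite, so all genes shared one spread. Of the T cell clusters that markers place in a CD8 (3 and 11) or CD4 (9 and 13) subset, 3 and 9 had at least 30 cells in every library and were also fitted by themselves, a choice made once the clusters were seen and before any gene was tested. Each of these 2 lies within the T cell-like class, so its fit is not independent of that of the class. Interactions between classes used the same test with the library as a block. DESeq2 1.42.0 gave the second test. Shares were tested with edgeR on cell counts with all kept cells as the offset, and since the trend could not be fitted on so few classes, a common dispersion was used, a choice made after seeing the data. Two-sided exact permutation tests stand beside single shares. Tnf was counted per cell after thinning each cell to 1000 UMIs without replacement (seed 1), which left out 4, 2, 10 and 6 monocyte-like cells.

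The 27 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, two-sided, adjusted over 247 pairs of list and fit with at least 5 measured genes. Of these pairs 109 passed, 67 up and 42 down, and with an estimated correlation 0 did. Which of them are described in each fit was chosen after seeing the list results. No described list had a median, mean and test of different sign. Of all list symbols, Mx2 and Atp5md were not found under those names. Named genes follow a rule fixed in advance: adjusted p under 0.05, both stress libraries on the same side of both controls, mean of at least 20 CPM, then the 10 largest rises and falls (5 each in NK or ILC1-like, plasma cell-like, cDC2-like and the 2 T cell clusters), up to 4 members of each described list by smallest p, and 11 preset genes in myeloid cells. Where no gene passed, the 5 of smallest p in each direction are given. Some genes that met these rules are not reported here. Predicted genes and receptor segments were counted and not named, as were 3 monocyte-like, 4 B cell-like, 22 plasma cell-like, 8 cluster 3 and 19 cluster 9 genes under 20 CPM.

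On simulated data made from each class, the fits recovered 10 to 93% of 2-fold and 86 to 100% of 4-fold changes, with 3 to 45 false calls per fit. The monocyte-like fit recovered 54 and 99% with 16 false calls, the macrophage-like fit 22 and 96% with 13, and the interaction test 14 and 73% with 5. Camera gave a p of 7.09e-09 to a raised list and a p under 0.05 to 5 of 100 unchanged lists.

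The alternatives were DESeq2's size factors, no filter on low counts, DESeq2's Wald test, the replicate number as a block, doublets kept, a mitochondrial limit of 25%, resolution 2.0, equal cells per library, each library left out in turn, and for lists an estimated correlation, fry and the block. A fit without a library leaves a group with 1 sample, which is assumed to vary like the others. Chosen after seeing the data were cluster 4 undivided, macrophage-like cells without cluster 18, B cell-like cells with clusters 5 and 10, the parts of clusters 3 and 9 at resolution 2.0, and cells other than fibroblast-like and epithelial-like cells. ILC2-like, cDC1-like, neutrophil-like, fibroblast-like and epithelial-like cells had too few cells in a library for a fit. V(D)J segment usage was not analysed here. Figures were drawn with matplotlib 3.10.9.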

Results

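Single-cell RNA-seq was measured in leukocytes sorted for CD45, a surface protein of blood-derived cells, from the whole colon of wild-type C57BL/6 mice. Mice had been restrained daily for 7 days, a common rodent model of psychological stress, or had received the control treatment, with 2 libraries per group. The deposited count matrices held 2941 and 6124 barcodes in controls 1 and 2, and 10259 and 5591 in stress 1 and 2, with 13806189, 21465320, 37010518 and 39074920 unique molecular identifiers (UMIs). After filtering, 2486, 5343, 7636 and 3942 cells remained, with medians of 2904, 2657, 2092 and 4375 UMIs per cell, so the shallowest and the deepest library were both from stressed mice. Of the barcodes, 12.9, 11.1, 18.8 and 26% held more than 10% mitochondrial UMIs and were left out. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples. Every log2 change is stress minus control, SE is the error of the fit, and levels are CPM (counts scaled to equal library size) as mean ± SD with n = 2 per group. A gene or list is said to rise or fall only where its adjusted p was under 0.05 in edgeR for genes and in limma's camera for lists.

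The first comparison asks whether the make-up of the sorted leukocytes differed with stress. Plasma cell-like cells made up 5.35% ± 3.12 of kept cells in controls and 14% ± 2.39 under stress (SD, n = 2), and monocyte-like cells 2.63% ± 1.52 and 6.86% ± 0.492. Neutrophil-like cells took 0.095% ± 0.0775 and 0.741% ± 0.566, and the dividing cells of cluster 16 (Top2a) 0.585% ± 0.139 and 1.55% ± 0.0015. In the other direction, group 2 innate lymphoid (ILC2-like) cells, which make type 2 cytokines, took 2.41% ± 1.77 and 0.438% ± 0.0099, NK or ILC1-like cells 2.99% ± 1.18 and 1.07% ± 0.067, and cDC1-like cells 0.965% ± 0.570 and 0.379% ± 0.146. No class passed the test. B cell-like cells, the largest class, took 35.9% ± 11.5 and 39.3% ± 1.62, and T cell-like cells 25.3% ± 10.7 and 21.1% ± 1.94. Macrophage-like cells took 9.53 and 0.992% of the controls against 1.23 and 3.20% of the stress libraries, so the controls lay on both sides of the stress libraries. Fibroblast-like cells, which lack CD45, took 9.61% of control 1 and at most 0.457% of any other library. Cluster 10, which was not named, took 2.21% ± 0.798 and 5.42% ± 0.652, and cluster 5, led by Egr3, 8.15% ± 1.74 and 4.36% ± 2.69.

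The edgeR test on cell counts called 0 of 15 classes and clusters, and 3 were under an unadjusted p of 0.05: neutrophil-like (log2 2.82, SE 1.05), ILC2-like (-2.45, SE 0.93) and fibroblast-like cells (-4.13), each with an edgeR adjusted p of 0.122. The two-sided exact permutation test called 0 as well, since its smallest possible p with 2 against 2 libraries is 0.333. Monocyte-like cells gave 1.39 (SE 0.86, edgeR adjusted p = 0.244) and an exact permutation p of 0.333. As a share of monocyte-like, macrophage-like and dendritic cells together they took 25.9% ± 7.96 in controls and 59.6% ± 7.48 under stress (exact permutation p = 0.333). ILC2-like cells passed without control 2 (-3.05), and both ILC2-like (-2.56) and neutrophil-like cells (2.72) passed among cells other than fibroblast-like and epithelial-like cells, an alternative chosen after seeing the data. Macrophage-like cells turned to 1.14 without control 1. Marked doublets were left out of all shares (2.36, 1.71, 8.21 and 4.48% of the cells of the 4 libraries), the CD45 sort decided which cells could be counted, and the median depth differed as given above.

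**Figure D1:**
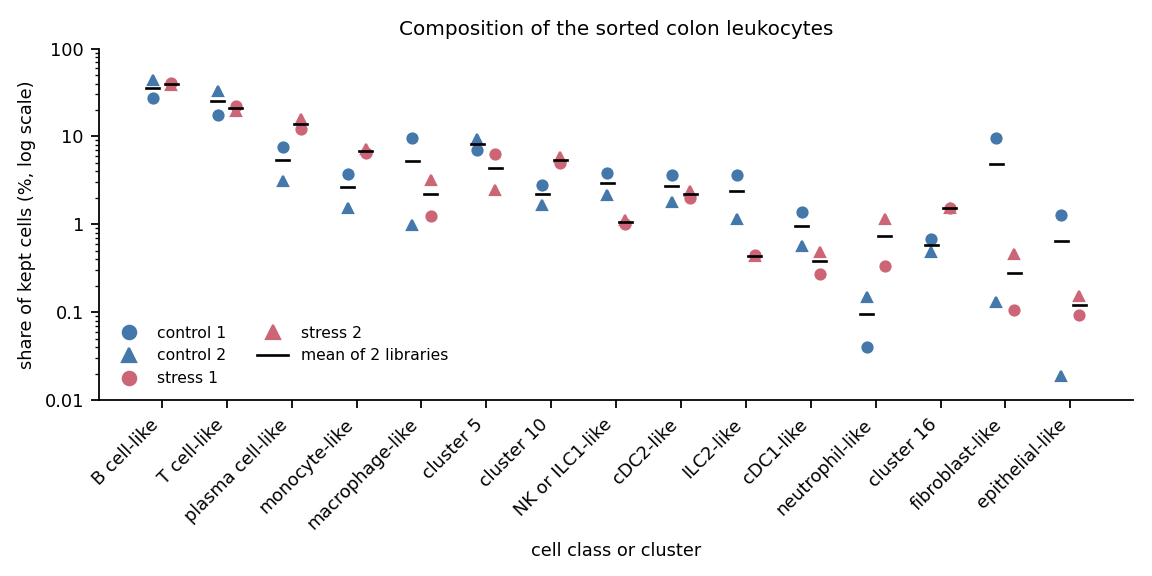
Share of kept cells (percent, log axis) of each class or cluster (horizontal axis), with 1 point per library, controls blue and stress red, and a line at the mean of 2 libraries. Monocyte-like cells took 3.70 and 1.55% of the control libraries and 6.51 and 7.2% of the stress libraries, and fibroblast-like cells stood out in control 1 alone.

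The comparison of all kept cells summed per library asks which genes differed with stress in the sorted tissue as a whole. Transcripts of dividing cells stood higher in both stress libraries, with Mki67, a nuclear protein of cycling cells, at 39.9 ± 6.31 CPM in controls and 107.4 ± 11.8 under stress, and Top2a, the DNA topoisomerase of replicating cells, at 38.8 ± 1.34 and 84.6 ± 10.8. Nuggc, a germinal centre GTPase, went from 11 ± 1.83 to 29.3 ± 2.26 CPM. Tob1, an inhibitor of proliferation, stood at 58.3 ± 1.44 CPM in controls and 28.9 ± 0.693 under stress, and Ramp1, a subunit of the receptor for the neuropeptide CGRP, at 45.7 ± 1.31 and 22.3 ± 1.85. None of these genes passed the adjusted test. The 5 genes with the smallest p in each direction above 20 CPM also held Arid3a (log2 1.18), Hist1h2ap (1.43), Tubb2a (-1.12), Pdlim1 (-1.21) and Rgcc (-1.05), all at an edgeR adjusted p of 0.711. The edgeR fit called 0 of 13101 genes, with 884 under an unadjusted p of 0.05, and DESeq2 called 140 (81 up, 59 down). Without control 1 the edgeR fit called 3107 genes and without control 2 it called 3284.

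Gene lists moved in the same cells. Among 30 cell cycle genes, 29 had a positive log2 change, with Cdk1 at 1.5 and Nusap1 at 1.10, and the list rose (camera adjusted p = 1.79e-25, adjusted p = 0.637 with an estimated correlation). Of the 30 genes, 0 rose, 0 fell and 30 did not pass over all genes, and 21 rose adjusted over the list alone. Cluster 16 (Top2a, Mki67) took 0.585% of control and 1.55% of stress cells in these sums and cluster 10 (Ube2c, Ccnb2) 2.21 and 5.42%, so the list was not separated from these shares. The interferon gamma response list rose with 23 of 24 genes positive, including Gbp5 (1.59), Tap1 (0.70) and Ido1 (1.89) (camera adjusted p = 2.69e-13, adjusted p = 0.637 with an estimated correlation). Of the 24 genes, 0 rose, 0 fell and 24 did not pass over all genes, and 0 passed adjusted over the list alone. Type I interferon response genes rose as a list with 27 of 27 positive, among them the nucleic acid sensor Zbp1 (1.15), Dhx58 (0.81) and Oas2 (1.08) (camera adjusted p = 2.92e-09, adjusted p = 0.661 with an estimated correlation). Of the 27 genes, 0 rose, 0 fell and 27 did not pass over all genes, and 0 passed adjusted over the list alone. Chaperones and other genes of the unfolded protein and integrated stress response rose as a list of 20, 17 of them positive, with Hsp90b1 (1.03), Manf (0.92), Hyou1 (0.61) and Asns (1.24) (camera adjusted p = 2.38e-10, adjusted p = 0.637 with an estimated correlation). Of the 20 genes, 0 rose, 0 fell and 20 did not pass over all genes, and 0 passed adjusted over the list alone. Secretory plasma cell-like cells made up 5.35% of control and 14% of stress cells in these sums, so the list was not separated from the share of that class. The type 2 cytokine list fell, with 9 of 9 genes negative, among them Gata3 (-1.33), Il17rb (-2.67), Il9r (-1.47) and the IL-33 receptor Il1rl1 (camera adjusted p = 1.72e-08, adjusted p = 0.637 with an estimated correlation). Of the 9 genes, 0 rose, 0 fell and 9 did not pass over all genes, and 5 fell adjusted over the list alone. ILC2-like cells, which Il1rl1 marks, took 2.41% of control and 0.438% of stress cells in the same sums. Genes of B cell activation and germinal centres rose as a list of 19, 11 of them positive, with Mef2b (1.17) and Gcsam (1.18) (camera adjusted p = 0.0134, adjusted p = 0.663 with an estimated correlation, 0.201 without control 2 and 0.1 without stress 1). Of the 19 genes, 0 rose, 0 fell and 19 did not pass over all genes, and 5 rose adjusted over the list alone.

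**Figure D2:**
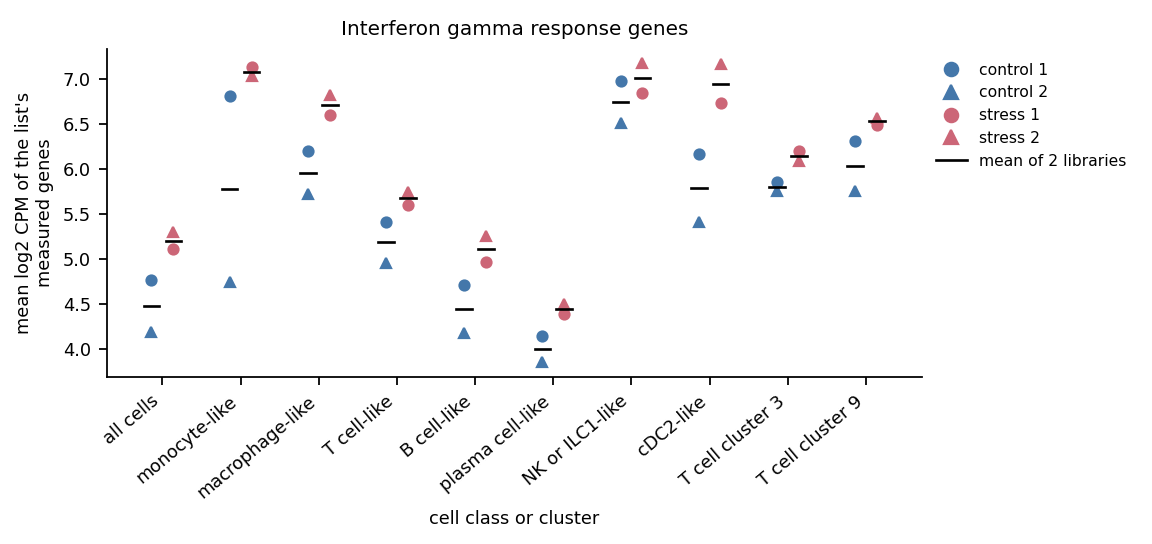
Mean log2 CPM over the measured genes of the interferon gamma response list (vertical axis) in each of the 10 fits (horizontal axis), with 1 point per library and a line at the mean of 2 libraries. Both stress libraries lie above both controls in 9 of the 10 fits, and in NK or ILC1-like cells control 1 lies above stress 1.

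Monocyte-like cells were compared to ask what stress did in recruited myeloid cells. Saa3, an acute-phase serum amyloid A protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 3.07 ± 4.34 to 46.7 ± 9.09 CPM (log2 3.89, SE 0.60, edgeR adjusted p = 0.0257), with 3 UMIs in controls and 213 under stress, a ratio of 15.4 with a 95% counting interval of 5.20 to 75.3. Klrb1b, an inhibitory lectin-like receptor, rose from 5.10 ± 1.46 to 35.5 ± 6.21 CPM (2.79, adjusted p = 0.0388), and Jaml, a junctional adhesion molecule of myeloid cells, from 33.6 ± 4.48 to 90.2 ± 11.7 (log2 1.43 ± 0.25 SE). The immunoglobulin transcripts Igha (2.31, adjusted p = 0.0162) and Jchain (1.84, adjusted p = 0.0388) rose, and these are made by plasma cells. Transcripts of T cells fell: Cd3g of the T cell receptor complex (-2.90, adjusted p = 0.0162), the receptor chain Trbc2 (-2.09, adjusted p = 0.0359) and the lymphocyte GTPase Gimap6 (-2.30, adjusted p = 0.0257). In all, edgeR called 11 of 7606 genes (5 up, 6 down), 3 of them under 20 CPM, and DESeq2 called 14. Leaving out control 1, control 2, stress 1 or stress 2 gave 476, 90, 6 and 0 calls, of which 11, 9, 2 and 0 were among the 11. Without stress 1, Saa3 (3.70), Klrb1b (2.97), Jaml (1.57), Cd3g (-2.94), Gimap6 (-2.43) and Trbc2 (-2.25) no longer passed. Without control 2 the same was true of Jchain (1.5) and Trbc2 (-1.54), and without stress 2 of every gene named here, with log2 changes from -2.78 for Cd3g to 4.10 for Saa3. At 25% mitochondrial UMIs Jchain (1.93, adjusted p = 0.0578) did not pass. With doublets kept Saa3 (3.82), Klrb1b (2.74), Jaml (1.44), Cd3g (-1.12), Trbc2 (-1.18) and Gimap6 (-1.60) did not pass. With cluster 4 undivided, a choice made after seeing the data, Klrb1b was 0.11 and Jaml -0.41, and Cd3g (-2.89), Trbc2 (-2.08) and Gimap6 (-2.02) did not pass either. Klrb1b and Jaml also failed in DESeq2 (adjusted p = 0.212 each) and with equal cells per library (2.64 and 1.42). Libraries held 92, 83, 497 and 284 monocyte-like cells, and 94, 83, 539 and 290 with doublets.

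In monocyte-like cells the interferon gamma response list rose with 22 of 22 genes positive, among them Tap1 (0.87), Igtp (0.86) and Gbp3 (1.07) (camera adjusted p = 1.96e-12, adjusted p = 0.661 with an estimated correlation). Of the 22 genes, 0 rose, 0 fell and 22 did not pass over all genes, and 2 rose adjusted over the list alone. TNF and NF-kB inflammatory genes rose as a list, 23 of 25 positive, with the prostaglandin synthase Ptgs2 (1.14), Tnfaip2 (1.41), the neutrophil chemokine Cxcl1 (2.08) and Nlrp3 (0.55) (camera adjusted p = 1.4e-07, adjusted p = 0.661 with an estimated correlation, 0.086 without control 2). Of the 25 genes, 0 rose, 0 fell and 25 did not pass over all genes, and 2 rose adjusted over the list alone. Glycolysis and hypoxia genes rose as a list, 20 of 20 positive, with the glucose transporter Slc2a1 (0.74), Pfkl (0.73), Vegfa (0.71) and Tpi1 (0.58) (camera adjusted p = 9.38e-09, adjusted p = 0.655 with an estimated correlation). Of the 20 genes, 0 rose, 0 fell and 20 did not pass over all genes, and 0 passed adjusted over the list alone. MHC class I presentation genes rose as a list, 16 of 17 positive, including H2-Q7 (0.81), Tapbp (0.58) and Psmb8 (0.53) (camera adjusted p = 8.48e-09, adjusted p = 0.661 with an estimated correlation). Of the 17 genes, 0 rose, 0 fell and 17 did not pass over all genes, and 5 rose adjusted over the list alone. The resident macrophage list fell, 9 of 12 genes negative, with the mannose receptor Mrc1 (-1.14), Maf (-0.83), Cx3cr1 (-0.72) and Tgfbr2 (-0.67) (camera adjusted p = 0.00472, adjusted p = 0.637 with an estimated correlation, 0.216 without control 1 and 0.0853 without stress 1). Of the 12 genes, 0 rose, 0 fell and 12 did not pass over all genes, and 3 fell adjusted over the list alone. Genes fixed in advance did not pass: Il1b (0.69), Il6 (0.62), Il10 (1.01), Csf1r (0.08), Ccl2 (0.14), the glucocorticoid receptor Nr3c1 (-0.43) and its targets Tsc22d3 (0.05), Fkbp5 (0.61) and Per1 (-0.05), with edgeR adjusted p from 0.538 to 0.976. Without control 1, however, Il1b (1.49, adjusted p = 1.28e-19), Il10 (7.82, adjusted p = 0.00288) and Ccl2 (0.95, adjusted p = 0.0224) passed, and without control 2 they stood at 0.18, 0.01 and -0.37, so these changes hung on which control was kept. Nos2 had too few counts to be tested.

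Tnf, the cytokine tumour necrosis factor (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), was examined on its own because monocytes are a known source of it. Its level in monocyte-like cells did not differ with stress, at 73.2 ± 71.6 CPM in controls and 74.2 ± 0.361 under stress, and the spread between the controls, 123.8 and 22.6 CPM, was the larger. With every cell thinned to 1000 UMIs, 12.5% of control 1 cells (95% Clopper-Pearson interval 6.41 to 21.3) and 1.24% of control 2 cells (0.0313 to 6.69) held a Tnf UMI, against 5.96% (4.02 to 8.44) and 7.55% (4.74 to 11.3) of stress 1 and stress 2 cells. The means were 6.87% ± 7.97 and 6.76% ± 1.13 (two-sided exact permutation p = 1), and without thinning 15.6% ± 10.2 and 23.7% ± 8.78 (exact permutation p = 0.667). Plasma cell-like cells, set beside them as a guide to free RNA, held a thinned Tnf UMI in 0, 0, 0 and 0.164% of cells at medians of 17763, 17763, 12076 and 22760 UMIs, against 5880, 6088, 4315 and 9131 in monocyte-like cells. Thinning takes more of the free RNA from deeper cells, and unthinned 0, 1.79, 0.64 and 1.3% of plasma cell-like cells held one. The first 3 of the thinned shares, 0 of 188, 159 and 936 cells, allow a share of cells with a thinned UMI of up to 1.60, 1.89 and 0.321% by a floor of 3 counts, and the interval of the method above reaches 1.94, 2.29 and 0.393%. The edgeR log2 change was -0.04 (SE 0.73, adjusted p = 0.993), 1.75 without control 1 and -0.82 without control 2, with both of these past the threshold on opposite sides. In macrophage-like cells Tnf stood at 141.2 ± 37.1 CPM in controls and 82.1 ± 12.1 under stress (log2 -0.86, edgeR adjusted p = 0.339). Intervals cover counting error only.

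**Figure D3:**
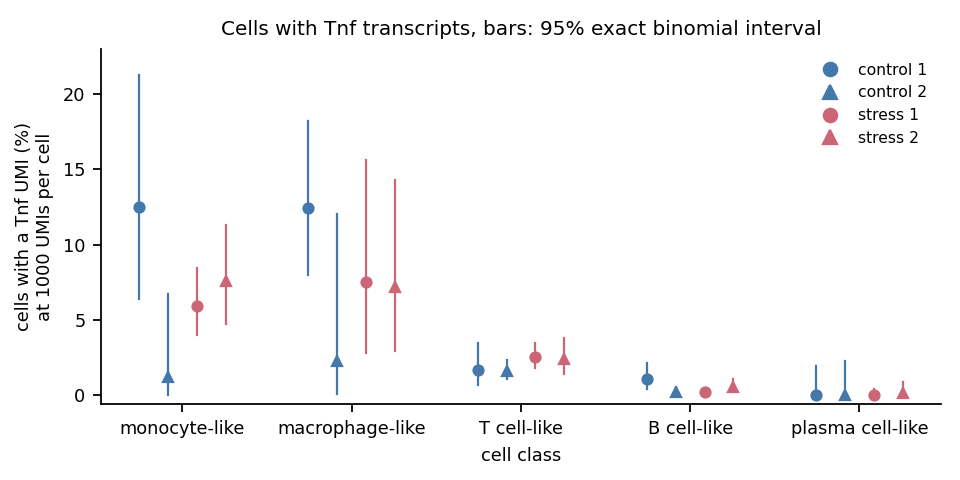
Share of cells with a Tnf UMI after thinning to 1000 UMIs (percent, vertical axis) in 5 cell classes (horizontal axis) of each library, with 95% Clopper-Pearson intervals as lines. In monocyte-like cells control 1 at 12.5% and control 2 at 1.24% lie on both sides of the stress libraries at 5.96 and 7.55%.

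Macrophage-like cells were compared as the tissue's phagocytes. Retnla, resistin-like alpha (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), fell from 3240 ± 617 to 454 ± 94.0 CPM (log2 -2.84, SE 0.27, edgeR adjusted p = 0.000267), as did the lectin Mgl2 (-1.65, adjusted p = 0.0113) and the ribonuclease Ear2 (-2.84, adjusted p = 0.0113). The macrophage elastase Mmp12 (-2.91), placental growth factor Pgf (-3.63, adjusted p = 0.00405) and the early response factor Egr1 (-1.64) fell as well. Plac8, a transcript of monocytes (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245), rose from 71.3 ± 10.0 to 323 ± 43.8 CPM (2.20, SE 0.26, adjusted p = 0.00192), and Ly6a, an interferon-inducible surface protein (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), from 112 ± 15.6 to 374 ± 23.5 (1.76, SE 0.25, adjusted p = 0.00558). Ly6i (3.4), a relative of Ly6a whose reads may be shared with it, complement factor Cfb (2.17), the fatty acid-binding Fabp5 (1.60) and the chemokine Ccl5 (1.96) rose, as did the plasma cell transcripts Igha (2.04), Iglc1 (2.14), Jchain (1.95) and Igkc (1.74). Rras2 (-2.66), Plxdc2 (-1.97), Rgcc (-1.88), the chemokine Ccl3 (-1.79) and the metallothionein Mt1 (-1.46) fell, so that edgeR called 26 of 5593 genes (12 up, 14 down) and DESeq2 22. With control 1, control 2, stress 1 or stress 2 left out, there were 194, 216, 52 and 23 calls, of which 24, 26, 24 and 15 were among the 26. Without stress 2, Cfb (1.98), Iglc1 (1.73), Jchain (1.38), Igkc (1.31), Fabp5 (1.33), Rras2 (-2.71), Plxdc2 (-1.44), Ccl3 (-1.39), Mgl2 (-1.43) and Egr1 (-1.44) no longer passed. Cfb (1.82) and Rras2 (-3.03) failed without control 1, and Mt1 without stress 1 (-1.14) or at 25% mitochondrial UMIs (-1.41, adjusted p = 0.053). Cfb (2.06), Fabp5 (1.09), Iglc1 (1.69) and Mmp12 (-2.94) did not pass without cluster 18, a choice made after seeing the data like that of cluster 4 undivided. In the latter Cfb (1.41), Fabp5 (0.76), Ccl5 (1.48), Ly6a (1.44), Mgl2 (-2.13), Mmp12 (-2.31), Pgf (-3.47), Mt1 (-1.97), Plxdc2 (-2.55) and Ccl3 (-1.32) did not pass. With doublets kept Cfb (2.14), Ccl5 (2.26), Fabp5 (1.49) and Ccl3 (-1.74) did not, and with equal cells Retnla (-3.56), Mmp12 (-3.27), Ly6i (4.49), Cfb (2.37), Fabp5 (1.21), Iglc1 (1.21), Igkc (1.84), Plxdc2 and Ccl3 (-1.52) did not. DESeq2 did not call Iglc1 or Plxdc2. Libraries held 237, 53, 94 and 126 of these cells, with stray monocytes untested as a source of Plac8 or Ly6i.

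Among 17 interferon gamma response genes in macrophage-like cells, 14 were positive, with Psmb9 (1.08), Tap1 (1.01) and Gbp3 (0.90), and the list rose (camera adjusted p = 1.18e-07, adjusted p = 0.637 with an estimated correlation). Of the 17 genes, 0 rose, 0 fell and 17 did not pass over all genes, and 5 rose adjusted over the list alone. The MHC class I presentation list rose with 14 of 16 positive, Psmb8 at 0.88 and H2-T22 at 0.76 (camera adjusted p = 2.62e-07, adjusted p = 0.637 with an estimated correlation). Of the 16 genes, 0 rose, 0 fell and 16 did not pass over all genes, and 4 rose adjusted over the list alone. Immediate early and dissociation genes, which cells also switch on while tissue is digested, fell as a list, 20 of 22 negative, with Jund (-1.02), Jun (-0.72) and Klf2 (-0.91) (camera adjusted p = 1.85e-06, adjusted p = 0.641 with an estimated correlation). Of the 22 genes, 0 rose, 1 fell and 21 did not pass over all genes, and 2 fell adjusted over the list alone. Glucocorticoid response genes fell as a list, 18 of 22 negative, with Il7r (-0.86), Errfi1 (-1.03) and, against the list, Sgk1 (0.99) (camera adjusted p = 0.00982, adjusted p = 0.661 with an estimated correlation, 0.295 without control 1 and 0.0749 without stress 2). Of the 22 genes, 0 rose, 1 fell and 21 did not pass over all genes, and 1 rose and 1 fell adjusted over the list alone. This list shares Zfp36 and Dusp1 with the immediate early and dissociation list. The resident macrophage list fell, 14 of 16 negative, with the tetraspanin Cd81 (-1.01), F13a1 (-0.89), Il10 (-1.15) and Adamdec1 (-0.77) (camera adjusted p = 0.0224, adjusted p = 0.81 with an estimated correlation), and it turned upward without control 1 (adjusted p = 0.29). Of the 16 genes, 0 rose, 0 fell and 16 did not pass over all genes, and 0 passed adjusted over the list alone. Genes fixed in advance did not pass, with Il1b at 0.44, Il6 at -0.22, Csf1r at -0.22, Ccl2 at -1.16, Nr3c1 at -0.34, Tsc22d3 at -0.33, Fkbp5 at -0.24 and Per1 at -0.36. Leaving out a control changed this for Il1b, which passed without control 1 (0.84, adjusted p = 9.14e-05), and for Il10 (-1.62, adjusted p = 2.21e-05) and Ccl2 (adjusted p = 4.73e-09), which fell without control 2, Ccl2 also with no filter on low counts (-1.17).

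A test of the difference asked whether stress acted differently in monocyte-like and macrophage-like cells. Mmp12 and Pgf, which fell in macrophage-like cells, had few UMIs in monocyte-like cells. Mmp12 had 1 in controls and 15 and 113 in stress 1 and 2, and Pgf 2, 4 and 18, so most came from stress 2. Their effects differed by 7.51 (SE 0.90, edgeR adjusted p = 0.00149) and 4.82 (adjusted p = 0.0391). Cxcl10 (1.46), Cxcl1 (2.42), Jaml (1.95) and Klrb1b (2.67) had a higher effect in monocyte-like cells. So had Isg15 (1.29) and Mt1 (1.47), mainly by negative changes in macrophage-like cells (-0.752 and -1.455). Fabp5 (-1.39) and Ly6i (-2.56) had a higher effect there. In all, 18 of 6604 genes differed (14 higher and 4 lower in monocyte-like cells). Leaving out control 1, control 2, stress 1 or stress 2 gave 103, 134, 33 and 16 calls, of which 13, 18, 14 and 8 were among the 18.

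T cell-like cells were compared to ask what stress did in lymphocytes that make inflammatory cytokines. Il22, a cytokine acting on the epithelium, stood at 26 ± 5.38 CPM in controls and 335 ± 246 under stress (log2 3.73). The metalloprotease Adam19 (1.22), the inflammatory caspase Casp4 (1.60) and Etv6 (1.08) were higher in value, and Rgcc (-1.82), Tob1 (-0.97), Tfb2m (-1.14), the protease Ctsl (-1.17) and Gadd45a (-0.90) lower, at edgeR adjusted p from 0.333 to 0.567. The edgeR fit called 0 of 9896 genes, with 724 under an unadjusted p of 0.05, and DESeq2 called 8 (7 up, 1 down). Without control 1 it called 1810, without control 2 201 and without stress 1 3. Control 2 held 702 and 526 of its 1752 T cell-like cells in the naive-like clusters 7 (Lef1) and 11 (Cd8b1), while clusters 3 (Gzma) and 9 (Icos) held 183 and 164 of 440 cells in control 1, 496 and 466 of 1715 in stress 1, and 347 and 250 of 777 in stress 2.

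Among 15 T helper 17 genes, 14 were positive in T cell-like cells, with Batf (0.92), Il1r1 (1.60) and Ccr6 (1.10), and the list rose (camera adjusted p = 8.81e-10, adjusted p = 0.661 with an estimated correlation, 0.318 without control 2). Of the 15 genes, 0 rose, 0 fell and 15 did not pass over all genes, and 5 rose adjusted over the list alone. T helper 1 and cytotoxic genes rose as a list, 16 of 20 positive, with Tnf (0.47), Ifng (1.24), Ccl3 (1.06) and Il12rb2 (0.99) (camera adjusted p = 3.05e-06, adjusted p = 0.661 with an estimated correlation). Of the 20 genes, 0 rose, 0 fell and 20 did not pass over all genes, and 1 rose adjusted over the list alone. Interferon gamma response genes rose as a list, 18 of 22 positive, with Gbp5 (1.59), Gbp6 (1.24) and Irgm1 (0.88) (camera adjusted p = 4.9e-08, adjusted p = 0.661 with an estimated correlation, 0.118 without control 2). Of the 22 genes, 0 rose, 0 fell and 22 did not pass over all genes, and 5 rose adjusted over the list alone. Cell cycle genes rose as a list, 15 of 22 positive, with Mki67 (1.78), Pclaf (1.48), Tpx2 (2.25) and Top2a (0.77) (camera adjusted p = 2.28e-07, adjusted p = 0.637 with an estimated correlation). Of these 22 genes, 0 rose, 0 fell and 22 did not pass over all genes, and 9 rose adjusted over the list alone. The type I interferon response list rose with 19 of 23 positive, including Ifit1 (1.80), Ifi27l2a and Rtp4 (1.03) (camera adjusted p = 1.61e-05, adjusted p = 0.637 with an estimated correlation). Of the 23 genes, 0 rose, 0 fell and 23 did not pass over all genes, and 0 passed adjusted over the list alone.

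Cluster 9, the T cells led by Icos, holds helper and regulatory cells and was fitted by itself. Ifng, the cytokine interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), rose from 189 ± 28.1 to 585 ± 40 CPM (log2 1.64, SE 0.20, edgeR adjusted p = 1.33e-13). Granzyme Gzmb (1.75, adjusted p = 2.89e-15), the chemokine Ccl5 (1.94, adjusted p = 1.89e-21) and the IL-12 receptor chain Il12rb2 (2.33, adjusted p = 3.63e-09) rose with it. The T helper 17 cytokines Il17a (1.10, adjusted p = 0.000193), Il17f (1.84, adjusted p = 1.9e-11) and Il21 (2.57, adjusted p = 0.00418) rose too. Lrrc32, which holds latent TGF-beta on regulatory T cells (-2.33), Cd83 (-1.99), the stress-response factor Atf3 (-2.21), Id3 (-2.38), Epcam (-2.37) and Stmn2 (-3.32) fell. By the 20 CPM naming rule, Jchain (3.80), Igha (3.50), Igkc (2.82), Ermn (2.58) and Ccl4 (2.50) rose most, the first 3 plasma cell transcripts. In all, edgeR called 189 of 7072 genes (103 up, 86 down) and DESeq2 26, and edgeR's spread estimate was shared by all genes. With control 1, control 2, stress 1 or stress 2 left out, there were 339, 157, 65 and 59 calls, of which 143, 86, 52 and 52 were among the 189. Without control 1, Jchain (4.04), Stmn2 (-2.19), Epcam (-1.60) and Il17f (2.20) no longer passed, and without control 2 Jchain (3.54), Ccl4 (1.70), Lrrc32 (-0.87), Il17f (1.51) and Il21 (2.27) did not. Id3 (-1.61) did not pass without stress 2. With doublets kept, at 25% mitochondrial UMIs and with equal cells, Il17a (1.06, 1.13 and 1.37), Il17f (1.76, 1.84 and 1.96), Lrrc32 (-2.48, -2.24 and -2.57) and Ccl4 (2.37, 2.47 and 1.2) did not pass. DESeq2 did not call Il17a (adjusted p = 1), Il21 (0.842, with 2 UMIs in each control), Ccl4 (0.842), Lrrc32 (0.12), Id3 (0.151), Epcam (0.0755) or Ermn (0.0837). Cd83 (-1.51) failed with doublets kept, and Jchain (4.66), Igha (4.32) and Igkc (3.74) with equal cells.

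The T helper 1 and cytotoxic list rose in cluster 9, 15 of 18 genes positive (camera adjusted p = 1.02e-13, adjusted p = 0.637 with an estimated correlation). Of the 18 genes, 9 rose, 1 fell and 8 did not pass over all genes, and 11 rose and 2 fell adjusted over the list alone. The T helper 17 list rose with 11 of 14 positive, including Batf (0.97) (camera adjusted p = 9.12e-09, adjusted p = 0.637 with an estimated correlation). Of the 14 genes, 6 rose, 0 fell and 8 did not pass over all genes, and 8 rose adjusted over the list alone. Genes of the regulatory T programme fell as a list, 9 of 13 negative, with the integrin Itgae at -0.88 (camera adjusted p = 0.00125, adjusted p = 0.637 with an estimated correlation, 0.0727 without stress 2). Of the 13 genes, 1 rose, 4 fell and 8 did not pass over all genes, and 1 rose and 6 fell adjusted over the list alone. Interferon gamma response genes rose as a list, 17 of 20 positive, with Gbp5 (1.81), Igtp (0.84) and Tap1 (0.66, not passing) (camera adjusted p = 7.46e-07, adjusted p = 0.661 with an estimated correlation, 0.306 without control 2). Of the 20 genes, 3 rose, 0 fell and 17 did not pass over all genes, and 7 rose adjusted over the list alone. Batf did not pass without stress 1 (0.88) or stress 2 (1.07). Itgae (-0.88, -0.85 and -0.88), Gbp5 (1.94, 1.73 and 1.90) and Igtp (0.72, 0.81 and 0.88) did not pass without control 2, stress 1 or stress 2. None of these 4 genes was called by DESeq2 (adjusted p = 0.157 for Batf, 0.69 for Gbp5 and Igtp and 1 for Itgae), and with equal cells Gbp5 (1.72), Igtp (0.84) and Itgae (-1.07) did not pass. Itgae also failed when blocked on the replicate number (adjusted p = 0.0533), at 25% mitochondrial UMIs (-0.79) and with no filter on low counts (-0.83). The regulatory part of the cluster held 66, 91, 134 and 57 cells of the 4 libraries against 98, 107, 332 and 192 in the helper part. Of the regulatory T genes, Itgae did not pass within the helper (-1.21) or the regulatory part (-0.11), Lrrc32 did not within the regulatory part (-1.46), and Cd83 passed within the regulatory part (-1.61) but not within the helper part (-0.38). Gbp5 (1.23) and Igtp (0.47) did not pass within the helper part, nor Batf (0.49) within the regulatory part.

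Cluster 3, the T cells led by Gzma, was also fitted by itself. Ctla4, an inhibitory receptor (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), rose from 85.4 ± 20.1 to 257 ± 47.9 CPM (log2 1.61, SE 0.20, edgeR adjusted p = 0.000384). The lipid flippase Atp8a2 (2.94), the transporter Abcb1b (1.81) and Casp4 (1.54) rose as well. Ccrl2 (-2.08), Rgs16 (-1.66), Ctsl (-1.53), Cd200r2 (-1.40) and Phlda1 fell, the last from 87.7 ± 1.82 to 35.0 ± 2.52 CPM (adjusted p = 0.00404). The edgeR fit called 72 of 7794 genes (32 up, 40 down) and DESeq2 21. Leaving out control 1, control 2, stress 1 or stress 2 gave 85, 207, 64 and 57 calls, of which 46, 61, 44 and 37 were among the 72. Abcb1b (1.29) and Rgs16 (-0.84) did not pass without control 2, nor Casp4 (1.16) and Cd200r2 (-1.06) without stress 1, nor Rgs16 (-1.57) without stress 2. Abcb1b, Casp4, Ctsl, Cd200r2 and Rgs16 were not called by DESeq2 or when blocked on the replicate number, and Abcb1b (1.59), Ccrl2 (-1.68), Cd200r2 (-1.10) and Rgs16 (-2.15) not with equal cells. The make-up of the cluster differed between groups: at resolution 2.0 its Gzma part held 46, 60, 310 and 214 cells of the 4 libraries and its Cd160 part 137, 191, 186 and 132. Within the Cd160 and Gzma parts Ctla4 changed by 1.53 and 0.80, Cxcr6 by 0.69 and 0.23 and Nfkbia by -0.62 and -0.09, none passing. Ccrl2 changed by -2.84 and -1.11, Ctsl by -0.87 and -1.94, Sgk1 by -1.15 and -0.67 and Zfp36 by -0.90 and 0.03, again none passing, so some changes were larger within a part than in the whole cluster. Phlda1 passed in the first (-1.43) and Atp8a2 in the second (2.64).

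The T helper 1 and cytotoxic list rose in cluster 3, 16 of 20 genes positive, with the chemokine receptor Cxcr6 (1.07), Ccl3 (0.64) and Klrg1 (2.47, 3 UMIs in controls and 34 under stress, ratio 6.05, interval 1.90 to 30.8), Klrd1 at -0.38 (camera adjusted p = 2.79e-07, adjusted p = 0.637 with an estimated correlation). Of these 20 genes, 3 rose, 0 fell and 17 did not pass over all genes, and 7 rose adjusted over the list alone. Glucocorticoid response genes fell as a list, 14 of 20 negative, with the RNA-binding Zfp36 (-0.78), the kinase Sgk1 (-0.97), Errfi1 (-0.88) and the NF-kB inhibitor Nfkbia (camera adjusted p = 0.000412, adjusted p = 0.637 with an estimated correlation). Of these 20 genes, 0 rose, 4 fell and 16 did not pass over all genes, and 9 fell adjusted over the list alone. Immediate early and dissociation genes fell as a list, 18 of 21 negative, with Ier5 (-0.69), the activation gene Nr4a1 (-0.61) and Jund (-0.68) (camera adjusted p = 6.49e-07, adjusted p = 0.663 with an estimated correlation). Of the 21 genes, 0 rose, 1 fell and 20 did not pass over all genes, and 9 fell adjusted over the list alone. Interferon gamma response genes rose as a list, 13 of 17 positive, with Tap1 (0.64), Psmb9 (0.51) and the inhibitor Socs1 at -0.60 (camera adjusted p = 0.00042, adjusted p = 0.637 with an estimated correlation, 0.081 without control 2). Of the 17 genes, 1 rose, 0 fell and 16 did not pass over all genes, and 4 rose and 1 fell adjusted over the list alone. Without control 1, Cxcr6 (1.02) and Errfi1 (-0.73) did not pass, and without control 2 Sgk1 (-0.88) did not. Cxcr6 (0.67), Zfp36 (-0.79), Sgk1 (-0.91) and Nfkbia (-0.77) did not pass without stress 1, nor Zfp36 (-0.76), Sgk1 (-1.05), Errfi1 (-0.60) and Nfkbia (-0.66) without stress 2. None of Cxcr6, Zfp36, Sgk1, Errfi1 and Nfkbia passed when blocked on the replicate number, and only Nfkbia of these was called by DESeq2.

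B cell-like cells were compared to ask whether stress reached the largest leukocyte class. Zbp1, a nucleic acid sensor induced by interferon (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), rose from 21 ± 5.11 to 46.8 ± 1.52 CPM (log2 1.25, SE 0.20, edgeR adjusted p = 0.00794). Mpeg1, the pore-forming perforin-2 (ENSMUSG00000046805, chromosome 19, 12460779 to 12465283), rose from 11.9 ± 3.27 to 29.9 ± 0.714 (1.45, SE 0.23, adjusted p = 0.00794). The interferon-inducible GTPase Irgm1 (1.33), Pmepa1 (1.16), Trib2 (1.01), the cyclin Ccnd2 (0.96), AU020206 (0.95) and the plasma cell transcripts Igha (2.66, adjusted p = 4.72e-08) and Jchain (2.66, adjusted p = 8.74e-09) rose. The kinase Pim1 fell from 236 ± 24.2 to 111 ± 26 CPM (adjusted p = 0.00794), and Asph (-1.40), the tubulins Tuba1a (-0.99) and Tubb4b (-0.91), Tcp11l2 (-0.95) and the iron-sulfur assembly factor Isca1 (-0.95) fell. Across the class, edgeR called 19 of 9767 genes (13 up, 6 down), 4 of them under 20 CPM, and DESeq2 called 12. With control 1, control 2, stress 1 or stress 2 left out, there were 404, 44, 142 and 7 calls, of which 19, 8, 19 and 2 were among the 19. Without control 2, Mpeg1 (1.07), Irgm1 (1.02), Zbp1 (0.93), Pmepa1 (0.81), Trib2 (0.67), Ccnd2 (0.63), AU020206 (0.93) and Asph (-0.84) no longer passed. Without stress 2 only Igha and Jchain did, with the others from -1.12 (Asph) to 1.40 (Mpeg1). With clusters 5 and 10 added to the class, a choice made after seeing the data, 0 genes passed, Igha (0.88) and Jchain (0.77) included. DESeq2 did not call Irgm1, Trib2, Ccnd2, AU020206 or Asph. Asph (-1.29) also failed with doublets kept, Asph (-1.37) and Ccnd2 (0.93) at 25% mitochondrial UMIs, and Zbp1 (0.97) and Trib2 (0.96) with equal cells. The cluster with the most B cell-like cells was 0 in control 1 and control 2 (317 of 689 and 1571 of 2350), 1 in stress 1 (1233 of 3090) and 8 in stress 2 (704 of 1505).

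In B cell-like cells the interferon gamma response list rose, 18 of 19 genes positive, with Gbp7 (1.24), Tap1 (0.64) and the MHC class I activator Nlrc5 (0.93) (camera adjusted p = 3.71e-15, adjusted p = 0.637 with an estimated correlation). Of the 19 genes, 1 rose, 0 fell and 18 did not pass over all genes, and 12 rose adjusted over the list alone. Type I interferon response genes rose as a list, 22 of 22 positive, with Slfn5 (1.26) and Stat2 (0.91) (camera adjusted p = 1.45e-14, adjusted p = 0.637 with an estimated correlation). Of these 22 genes, 1 rose, 0 fell and 21 did not pass over all genes, and 9 rose adjusted over the list alone. Genes of B cell activation and germinal centres rose as a list, 10 of 15 positive, with Mki67 (2.19), Fas, Mef2b (1.32) and Egr2 (1.19) (camera adjusted p = 0.00564, adjusted p = 0.712 with an estimated correlation), but not without stress 1 (adjusted p = 0.507), and downward without control 2 (adjusted p = 0.813). Of the 15 genes, 0 rose, 0 fell and 15 did not pass over all genes, and 4 rose adjusted over the list alone. The T helper 1 and cytotoxic list rose, 8 of 10 positive, with the chemokine receptor Cxcr3 (2.85, 2.89 without control 2 and 2.79 without stress 2, neither passing), Gzma (1.65), Gzmb (2.83) and Ccl5 (1.39) (camera adjusted p = 0.00108, adjusted p = 0.637 with an estimated correlation, 0.0597 without control 2). Of the 10 genes, 1 rose, 0 fell and 9 did not pass over all genes, and 4 rose adjusted over the list alone. Few UMIs carry these transcripts of T and NK cells, with 1, 4, 27 and 28 for Cxcr3 and 1, 4, 12 and 42 for Gzmb in the 4 libraries, and free RNA or doublets of T cells were not tested as their source. A test of the difference between the stress effects in T cell-like and B cell-like cells called 0 of 10684 genes in edgeR, with 802 under an unadjusted p of 0.05, and no other tool was run on it. Leaving out control 1, control 2, stress 1 or stress 2 gave 68, 2, 31 and 11 calls.

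**Figure D4:**
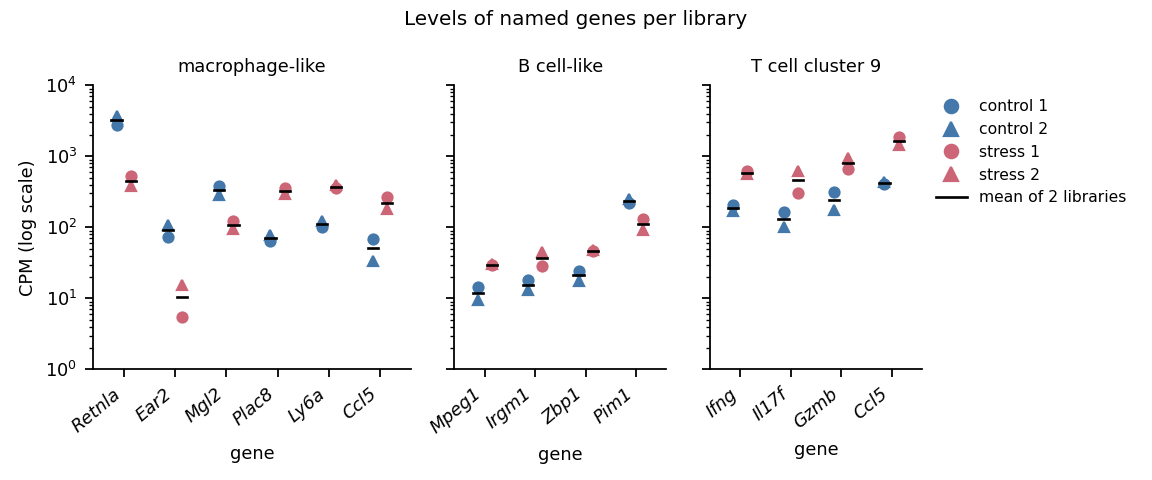
CPM per library (log axis) of named genes (horizontal axis) in macrophage-like cells, B cell-like cells and T cell cluster 9, with 1 point per library, controls blue and stress red, and a line at the mean of 2 libraries. In macrophage-like cells Retnla fell from a mean of 3240 to 454 CPM and Plac8 rose from 71.3 to 323, and in cluster 9 Ifng rose from 189 to 585.

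Plasma cell-like cells, which secrete antibody, were also compared. Basp1, a membrane-bound signalling protein (ENSMUSG00000045763, chromosome 15, 25363277 to 25413764), fell from 244 ± 58.0 to 70.9 ± 0.375 CPM (log2 -1.78, SE 0.18, edgeR adjusted p = 0.00406). Ly6d, a marker of earlier B lineage cells (-1.5, adjusted p = 0.0174), the IgG1 constant region Ighg1 (-1.52), Tmem176a and Tmem176b (both close to -1.35) fell. Ccl5 (2.17) and Gzma (1.12), transcripts of T and NK cells, and Dnm3 (0.91) rose. The fit called 41 of 9306 genes (9 up, 32 down), 22 of them under 20 CPM, and DESeq2 called 64. With control 1, control 2, stress 1 or stress 2 left out, there were 238, 291, 26 and 31 calls, of which 41, 41, 11 and 18 were among the 41. Without stress 1, Ccl5 (2.08), Gzma (1.02), Dnm3 (0.97), Ighg1 (-1.29), Tmem176a (-1.21) and Tmem176b (-1.21) no longer passed, and without stress 2 Dnm3 (0.85) did not. With doublets kept and with equal cells Ccl5 (1.61 and 1.37), Gzma (1.86 and 0.86), Dnm3 (0.87 and 0.92) and Ighg1 (-1.76 and -1.04) did not pass. Ccl5 (2.14) and Ighg1 (-1.26) failed at resolution 2.0, and Dnm3 in DESeq2 and blocked on the replicate number. Libraries held 188, 168, 937 and 617 plasma cell-like cells.

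Interferon gamma response genes in plasma cell-like cells rose as a list, 16 of 18 positive, with the GTPases Gbp2 (1.18), Gbp4 (1.05, not passing) and Irgm1 (camera adjusted p = 9.06e-08, adjusted p = 0.637 with an estimated correlation). Of the 18 genes, 2 rose, 0 fell and 16 did not pass over all genes, and 7 rose and 2 fell adjusted over the list alone. The MHC class II presentation list fell, 11 of 13 negative, with the protease Ctss (-1.06), H2-Ob (-1.09) and, not passing, H2-Aa (-1.05) and Cd74 (-0.77) (camera adjusted p = 2.89e-07, adjusted p = 0.637 with an estimated correlation). Of the 13 genes, 0 rose, 2 fell and 11 did not pass over all genes, and 3 fell adjusted over the list alone. Immediate early and dissociation genes fell as a list, 19 of 21 negative, with Ppp1r15a (-0.98) and, not passing, Junb (-0.82), Ier2 (-0.57) and Atf3 (-1.98) (camera adjusted p = 1.66e-07, adjusted p = 0.637 with an estimated correlation). Of the 21 genes, 0 rose, 1 fell and 20 did not pass over all genes, and 6 fell adjusted over the list alone. Glucocorticoid response genes fell as a list, 18 of 22 negative, with the homing receptor Cxcr4 (-1.13) and, not passing, Nfkbia (-0.90), Mt1 (-1.06) and Mt2 (-0.86) (camera adjusted p = 5.76e-07, adjusted p = 0.637 with an estimated correlation). Of these 22 genes, 0 rose, 1 fell and 21 did not pass over all genes, and 5 fell adjusted over the list alone. Without stress 1 the calls of Gbp2 (1.30), Ctss (-1.07), H2-Ob (-1.05), Ppp1r15a (-0.99) and Cxcr4 (-0.96) were lost. Without stress 2 they were lost too (1.05, -1.05, -1.13, -0.96 and -1.32). So were those of Gbp2 (1.08), H2-Ob (-0.78) and Cxcr4 (-0.66) with doublets kept, Gbp2 (1.16) and Cxcr4 (-1.07) at resolution 2.0, Cxcr4 (-0.80) with equal cells and H2-Ob in DESeq2.

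NK or ILC1-like cells showed 1 rise besides plasma cell transcripts. Ctla4, the inhibitory receptor, rose from 75.5 ± 4.70 to 229 ± 22.3 CPM (log2 1.59, edgeR adjusted p = 0.0488, DESeq2 adjusted p = 0.469, and not passing with DESeq2's size factors at 0.0594 or without stress 2 at log2 1.47), and Jchain (2.04, adjusted p = 0.00597) and Igha (1.91, adjusted p = 0.00152) rose. The fit called 3 of 3981 genes (3 up, 0 down) and DESeq2 3, with 2 in both. Both other ways of dividing the 4 libraries into pairs called more, 6 and 9 genes, which was true of no other fit with calls. Leaving out control 1, control 2, stress 1 or stress 2 gave 18, 46, 32 and 8 calls, of which 3, 3, 3 and 2 were among the 3. Immediate early and dissociation genes fell as a list, 18 of 20 negative, with Junb (-0.62), Jund (-0.78), Gadd45b (-0.74) and, against the list, Klf2 (1.43) (camera adjusted p = 1.05e-05, adjusted p = 0.661 with an estimated correlation, 0.283 without stress 2). Of these 20 genes, 0 rose, 0 fell and 20 did not pass over all genes, and 1 rose and 4 fell adjusted over the list alone. TNF and NF-kB inflammatory genes fell as a list, 13 of 15 negative, with Ccrl2 (-1.23), the chemokines Ccl3 (-1.05) and Ccl4 (-0.59) and Nfkbia (-0.62) (camera adjusted p = 0.000217, adjusted p = 0.637 with an estimated correlation). Of the 15 genes, 0 rose, 0 fell and 15 did not pass over all genes, and 3 fell adjusted over the list alone. The regulatory T list, which holds inhibitory and activation receptors also made by NK cells, rose with 6 of 8 positive, Tnfrsf9 at 1.28, Gzmb at 1.51 and Icos at -0.73 (camera adjusted p = 0.000174, adjusted p = 0.637 with an estimated correlation). Of the 8 genes, 1 rose, 0 fell and 7 did not pass over all genes, and 3 rose adjusted over the list alone. Libraries held 95, 115, 78 and 44 of these cells.

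Among cDC2-like cells, interferon-induced genes rose. Irf7, the transcription factor that amplifies interferon production (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), rose from 16.4 ± 5.61 to 72.3 ± 11.9 CPM (SE 0.36, edgeR adjusted p = 0.0445), the GTPase Ifi47 from 24.3 ± 13.4 to 127 ± 20.3 (2.37, adjusted p = 0.0415) and Zbp1 from 22.6 ± 8.32 to 93.7 ± 0.926 (2.04, adjusted p = 0.0415). AA467197 (2.50) and the chromatin reader Zmynd8 (1.86) rose too. The metallothionein Mt2 fell from 76.2 ± 5.45 to 5.19 ± 1.44 CPM (-3.81, SE 0.40, adjusted p = 0.00681). Complement C1qb (-3.49) and the elastase Mmp12 (-2.85) fell in the same cells, as did the signalling ligand Wnt11 (-1.78) and the AP-1 factor Batf (-1.70). C1qb is among the leading genes of cluster 4 and macrophage-like cluster 18, and Mmp12 is a macrophage transcript. Here 5 T cell transcripts were lower in value too (median log2 -1.28). Cells or free RNA of other types were therefore not separated from a change within the class. The fit called 16 of 6018 genes (9 up, 7 down) and DESeq2 17. With control 1, control 2, stress 1 or stress 2 left out, there were 114, 413, 106 and 49 calls, of which 16, 16, 15 and 15 were among the 16, and every gene named here passed each time. DESeq2 did not call Irf7 (adjusted p = 0.0999) or Zmynd8 (0.0874), Mt2 (-1.95) failed at 25% mitochondrial UMIs, and Zmynd8 (2.05) at resolution 2.0. With equal cells AA467197 (2.46), Mmp12 (-2.42) and Zmynd8 (1.54) did not pass.

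The type I interferon response list rose in cDC2-like cells, 15 of 16 genes positive, with Trim30a (1.28) and Slfn5 (1.54) (camera adjusted p = 9.97e-17, adjusted p = 0.637 with an estimated correlation). Of the 16 genes, 2 rose, 0 fell and 14 did not pass over all genes, and 11 rose adjusted over the list alone. Interferon gamma response genes rose as a list, 18 of 18 positive, with the immunoproteasome subunits Psmb9 (0.95) and Psmb8 (0.69), Gbp3 (1.85) and Irf1 (camera adjusted p = 1.02e-13, adjusted p = 0.637 with an estimated correlation). Of the 18 genes, 0 rose, 0 fell and 18 did not pass over all genes, and 8 rose adjusted over the list alone. MHC class I presentation genes rose as a list, 14 of 17 positive, with Psmb10 (0.70) and H2-Q7 (0.72) (camera adjusted p = 4.68e-06, adjusted p = 0.637 with an estimated correlation). Of the 17 genes, 0 rose, 0 fell and 17 did not pass over all genes, and 5 rose adjusted over the list alone. The glucocorticoid response list fell, 11 of 20 negative, with Mt1 (-2.42), Cebpd (-1.09) and the annexin Anxa1 (-0.72) (camera adjusted p = 0.0117, adjusted p = 0.661 with an estimated correlation, 0.26 without control 1 and 0.0729 without stress 2). Of these 20 genes, 0 rose, 1 fell and 19 did not pass over all genes, and 4 fell adjusted over the list alone. Libraries held 90, 97, 154 and 94 of these cells, and 56 of them (1, 10, 26 and 19) were plasmacytoid DC-like, a cell type known for high Irf7.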

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

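The depth tests of the immunoglobulin and interferon patterns, the comparisons of UMIs per cell for the immunoglobulin and T cell patterns, and the form of the free RNA value of the interferon pattern, were chosen only after the results were seen.

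Stress effects differed between monocyte-like and macrophage-like cells in 18 genes, 4 of them unnamed class markers. The difference, monocyte-like minus macrophage-like on the log2 scale, was largest for Mmp12 (7.51), Pgf (4.82), Tmem63b (3.49), Klrb1b (2.67) and Cxcl1 (2.42), of which Mmp12 and Pgf rest on few monocyte-like UMIs. It was 1.95 for Jaml, 1.78 for Mmp19, 1.74 for Ecm1, 1.56 for Cd9, 1.47 for Mt1, 1.46 for Cxcl10 and 1.29 for Isg15. Fabp5 (-1.39) and Ly6i (-2.56) had the higher effect in macrophage-like cells. Mmp19, Ecm1, Cd9, Mt1 and Isg15 differed mainly by lower values there.

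Igha, a transcript of plasma cells, stood higher in both stress libraries, the shallowest and the deepest, than in both controls in 3 of 5 classes that do not make it (NK or ILC1-like, monocyte-like and macrophage-like cells), which cannot tell depth from the rest. Free RNA of plasma cells predicts that the ratio of Jchain to Igha in other classes equals that in plasma cells. The median ratio of ratios was 0.844 (0.449 to 1.00 over 5 classes and 4 libraries), which fits free RNA, and doublets with plasma cells would give it too. Free RNA also predicts like amounts per cell, and the 3 classes held 0.59 to 0.87 and 0.55 to 0.98 Igha UMIs per cell in controls 1 and 2 and 1.49 to 2.23 and 4.11 to 6.82 in stress 1 and 2. T cell-like cells of control 1 held 7.33 (2354 CPM against 1117 and 1196 under stress), and cDC2-like cells 109.8, 35.1 and 93.1 in controls 1 and 2 and stress 1 and 5.32 in stress 2. These 2 classes thus did not rise alike, and free RNA alone does not account for their higher values. In the other 3 the rise may reflect the larger plasma cell share of the stress libraries and not expression in the cells.

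T cell transcripts fell in monocyte-like cells. Free RNA of T cells enters all droplets of a library alike, so control B cell-like cells should hold as much per cell. For Cd3g, Lat, Icos and Trbc2 they held at most 0.0303 times the UMIs per monocyte-like cell, which excludes free RNA for these 4 genes. For Gimap6 and Gimap1 they held at least 2.50 times as many, so B cells hold these themselves and free RNA stays open. Median log2 changes elsewhere do not decide it: 0.16 in B cell-like cells (4 of the 6 genes, with Gimap6 and Gimap1) and -0.20 in plasma cell-like cells (Trbc2 -1.33). They were -1.24 in macrophage-like and -1.28 in cDC2-like (5 genes each) against -2.60 in monocyte-like cells. Doublets of monocytes and T cells predict that the fall shrinks without cells holding at least 2 UMIs of 8 other T cell markers. These were 5.44 and 9.64% of the controls and 1.41 and 3.17% of the stress libraries. The median shrank to -1.22. Icos went from -3.37 ± 0.53 to -0.28 ± 2.11 (SE), Trbc2 from -2.09 ± 0.34 to -0.80 ± 0.82 and Gimap1 from -2.27 ± 0.39 to -0.86 ± 0.76. The fall stayed larger for Gimap6 (-2.30 ± 0.35 to -1.57 ± 0.52), Lat (-2.94 ± 0.45 to -1.98 ± 1.12) and Cd3g (-2.90 ± 0.39 to -2.51 ± 1.22). No gene passed (edgeR adjusted p from 0.156 to 0.969), as changes shrank and few UMIs were left. In controls Cd3g kept 5 of 22 and 15 UMIs and Icos 1 of 16 and 9. Trbc2 kept 6 of 18 and 35 and Lat 5 of 11 and 19. The rest lay in cells with other T cell markers, which argues against a change within monocytes for these 4, with Gimap6 and Gimap1 left open. With marked doublets kept the median was -1.48 and no gene passed. Leaving them out took stress 1 from 539 to 497 cells but left 83 in control 2.

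Interferon gamma response genes stood higher with stress across classes. Depth predicts that the shallowest and the deepest library, both from stress, fall on opposite sides of the controls, but both lay above both controls in 9 of 10 fits. Free RNA of one source predicts a like addition of UMIs to all classes. The list gained 19.6 and 17.9 UMIs per monocyte-like cell in stress 1 and 2, 13.1 and 10.2 per cDC2-like cell, 0.211 and -0.746 per plasma cell-like cell, so neither explanation held. The size of the monocyte-like gain rests in part on control 2, which stood apart at 10.3 UMIs against 27.2 in control 1 and 38.3 and 36.6 in stress 1 and 2. Control 1 still lay below both, while plasma cell-like cells held 13.45 to 14.91 in all 4 libraries, so the addition was unequal against control 1 as well. A response of the cells to interferon in stressed mice could give this pattern, but a difference in handling or batch, which the labels do not give, could too.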

How the results depend on the processing

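Cluster 4 undivided, macrophage-like cells without cluster 18, B cell-like cells with clusters 5 and 10, the parts of clusters 3 and 9, and the counts without fibroblast-like and epithelial-like cells were chosen only after the results were seen.

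Libraries decided most counts of changed genes. With each library left out in turn the counts lay between 0 and 3284 for all cells, 0 and 476 for monocyte-like, 23 and 216 for macrophage-like, 0 and 1810 for T cell-like, 7 and 404 for B cell-like, 26 and 291 for plasma cell-like, 8 and 46 for NK or ILC1-like and 49 and 413 for cDC2-like cells. They lay between 57 and 207 for cluster 3, 59 and 339 for cluster 9, 16 and 134 for the difference between monocyte-like and macrophage-like cells, and 2 and 68 for that between T cell-like and B cell-like cells. Between 0 and 1 share was called. The Tnf change in monocyte-like cells ranged from -0.82 to 1.75, and was 0.02 with no filter on low counts. The cause was not tested beyond the lone library left in a group.

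With no filter on low counts, many more genes were tested and the calls were 181 in monocyte-like, 97 in macrophage-like, 143 in T cell-like, 151 in B cell-like, 283 in plasma cell-like, 21 in NK or ILC1-like and 215 in cDC2-like cells and 175 in cluster 3, and 56 and 115 for the differences between myeloid and between lymphoid classes. DESeq2's Wald test called 140 genes in all cells, 8 in T cell-like, 12 in B cell-like and 64 in plasma cell-like cells, 21 in cluster 3 and 26 in cluster 9. Doublets kept gave 3 in monocyte-like, 6 in NK or ILC1-like and 26 in cDC2-like cells and 97 in cluster 9. Equal cells per library gave 14 in macrophage-like, 30 in B cell-like and 5 in NK or ILC1-like cells and 62 in cluster 9, from fewer cells. Resolution 2.0 gave 39 in B cell-like and 42 in cDC2-like cells. Cluster 4 undivided gave 47, B cell-like cells with clusters 5 and 10 gave 0, the Cd160 and Gzma parts of cluster 3 gave 4 and 6, and the helper and regulatory parts of cluster 9 gave 74 and 12. The parts have fewer cells and differ in their share between groups, and within the parts of cluster 3 some changes shrank and others grew, so neither was singled out as the reason. The cause of the other differences was not tested. The 109 list calls fell to 0 with an estimated correlation and to 0 with fry. Of the shares, 1 was called with doublets kept and 1 at resolution 2.0, the fibroblast-like share each time, and 2 (ILC2-like and neutrophil-like) without fibroblast-like and epithelial-like cells.

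The replicate number shares only a number between groups: across genes, the difference between controls 1 and 2 correlated with that between stress 1 and 2 at -0.24 in all cells and from -0.36 (T cell-like) to 0.15 (cDC2-like) over the fits, so the numbers do not pair the libraries. Blocked on it, the calls were 49 in monocyte-like, 50 in macrophage-like, 68 in B cell-like, 62 in plasma cell-like, 8 in NK or ILC1-like and 101 in cDC2-like cells and 13 in cluster 3, and the Tnf change was 0.11.

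Directions turned as follows, and the cause was not tested. With each library left out in turn, the log2 change of the share ranged from -2.12 to 1.14 for macrophage-like, -0.16 to 0.50 for B cell-like, -0.64 to 0.25 for T cell-like, -0.72 to 0.27 for cDC2-like, -5.5 to 0.98 for fibroblast-like and -3.43 to 2.51 for epithelial-like cells, the last 2 turning without control 1. The B cell-like share gave 0 with TMM over classes, and without B and plasma cell-like cells the T cell-like share gave 0.01 and the cDC2-like share 0.06. In monocyte-like cells the same fits ranged from -0.11 to 0.32 for Csf1r, -0.37 to 0.95 for Ccl2, -0.06 to 0.20 for Tsc22d3 and -0.18 to 0.11 for Per1 (0.04 without stress 2), which also turned with no filter (0.02) and equal cells (0.25). Ccl2 was -0.14 without stress 2. With cluster 4 undivided, Jaml (-0.41), Cxcl1 (-0.30), Il6 (-0.25), Il10 (-1.54), Csf1r (-0.14), Ccl2 (-0.97) and Tsc22d3 (-0.15) turned. In macrophage-like cells the fits without a library ranged from -1.62 to 0.09 for Il10, -1.38 to 0.11 for Adamdec1, -1.36 to 0.65 for Il6 (0.13 without control 2), -0.45 to 0.09 for Csf1r and -0.86 to 0.16 for Fkbp5. There F13a1 (0.22) and Tsc22d3 (0.10) turned with equal cells and Fkbp5 (0.16) with cluster 4 undivided. Ccl3 turned in the Cd160 and Gzma parts of cluster 3 (-0.06 and -0.23), Zfp36 in its Gzma part (0.03) and Ccl5 in the regulatory part of cluster 9 (-0.15).

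The 111 results past the threshold that the naming rule gave were tried in 1451 alternative fits, of which 1139 kept direction and call, 309 kept direction alone and 3 turned. The 167 that did not pass were tried in 2090, of which 370 passed in the same direction and 28 turned. In simulated data changes by a factor of 2 were recovered in 10% of genes of all cells, 18% of NK or ILC1-like and 22% of macrophage-like and of cDC2-like cells.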

Other observations

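The test within cluster 9 was planned after its gene results were seen, with its prediction written before it was run.

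Cluster 9 holds a helper part (98, 107, 332 and 192 cells) and a regulatory part (66, 91, 134 and 57 cells). A hypothesis was that Ifng, Il17f, Gzmb and Ccl5 rise because the stress libraries hold fewer regulatory cells within the cluster. In the helper part alone the median log2 change of the 4 genes was 1.73, with Ifng at 1.25 (edgeR adjusted p = 0.000334), Il17f at 1.42 (0.0192), Gzmb at 2.51 (2.46e-06) and Ccl5 at 2.03 (1.73e-06). Most of the rise stayed, so fewer regulatory cells do not account for it. Helper T cells may make more of the 4, but for Ccl5 and Gzmb free RNA or doublets of cluster 3 were not tested. Il17a, which is not among the 4, was 0.74 in the helper part (0.267) against 1.10 in the whole cluster. Ifng and Il17a lead the helper part at resolution 2.0, so the division itself rests partly on such genes. In the regulatory part alone Ccl5 had a log2 change of -0.15 and Gzmb of 1.29.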
